A study of Homo sapiens with 28 samples.

How the data were processed

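Poly(A) RNA libraries of 28 cultures were sequenced on an Illumina NovaSeq X after preparation with a KAPA mRNA HyperPrep kit, per the labels' protocols. All cultures came from KOLF2.2J, an established human induced pluripotent stem cell line, or from clones of it that carry a termination codon in 1 of 6 transcription factor genes. Per the submitters' processing notes, reads were handled with STAR and Salmon on GRCh38, and no versions, options or annotation release were given. The main values are the Salmon estimated counts per gene, deposited by the authors without scaling. A deposited companion table holds the same estimated counts rounded to whole numbers, each within 0.5 of the unrounded value. A separate table of whole-number counts per gene carries the name featureCounts, per the file name and headers, with no statement of strand or multi-mapping options. Another deposited table gives counts of reads per library that were unmapped, multi-mapping, ambiguous or in no feature. Tables in TPM and per transcript were not used.

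The tables list 38592 genes by Ensembl identifier, of which 38568 were matched to a symbol. Estimated counts were rounded to whole numbers before testing. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total count 15) within the libraries of each fit. Groups were compared with edgeR 4.0.16 in R 4.3.3: TMM factors, robust dispersion estimates, the quasi-likelihood F test and Benjamini-Hochberg adjustment, called at an adjusted p under 0.05. Standard errors of log2 fold changes are the sizes implied by the F statistic. CPM values of genes are TMM-scaled unless given as plain CPM, and are means ± SD over the libraries of a group. Means over gene lists per library are of log2 plain CPM.

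Samples were grouped by title. The 7 parental libraries of the DMRTA1, TBR1 and OVOL1 sets carry the edited gene and position in their labels, and were taken as unedited by their titles alone. DMRTA1 and OVOL1 clones were fitted with the parental libraries of their own set. PITX1, LMO2 and ZBTB7C clones share 3 parental libraries, and these 12 libraries entered 1 fit. The TBR1 set has 1 parental library, so the spread was pooled over the 10 organoid libraries, and that library was assumed to vary like the others. Each set was sequenced on 1 lane of its own, so set and lane cannot be told apart. The 12 comparisons were 6 of clones against parental libraries, 3 between clones of different genes in the shared set, 2 differences of effects between sets, and 1 of the parental line between the trophoblast sets.

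Before the data were examined, 27 gene lists were fixed, 20 for the organoids and 22 for the trophoblast cells. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, inter-gene correlation 0.01), two-sided, adjusted over the lists of a comparison. The test sets a list's shift against that of all other genes. It was repeated with the correlation estimated from the data. A list of 12 heat shock genes was added after seeing the data and was used only for values per library.

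The genes named are the targeted gene, and the 10 with the highest and the 10 with the lowest log2 fold change among genes with an adjusted p under 0.05. Those genes also needed an average log2 CPM of at least 1, every clone beyond every parental library, and a symbol that is not a clone, LINC, microRNA, antisense or similar name. Up to 4 called members of each list were added, or up to 2 with the smallest p where none was called. For differences between effects, 5 genes each way were taken without the condition on single libraries. Of the genes in the tables, 116 (XIST and Y-linked genes) are not reported singly. Positions are on GRCh38, with exons from GENCODE release 29.

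Alternatives were median-of-ratios factors, no filter on low counts, the featureCounts table, other samples in the fit, DESeq2 1.42.0, and leaving out each library in turn. For lists the estimated correlation was another. Leaving out TBR1 clones B03 and C10, or PITX1 clone B03 with ZBTB7C clone A11, was added after seeing the data. The edgeR steps were tested on simulated counts in which 200 genes were changed, with a single draw per comparison. Genes were drawn independently, so co-variation among libraries was not simulated. The adjustment is stricter where fewer genes change. Recovery in the real data may therefore be lower than the shares given here. At a 2-fold change 82.1% of changed genes were recovered for DMRTA1 (16126 genes), 7.5% for TBR1 (20041 genes), 86.6% for OVOL1 (14839 genes), 82.1% for PITX1 (16303 genes), 77.6% for LMO2 (16274 genes) and 71.6% for ZBTB7C (16281 genes). Of the genes called, the share that had not been changed was above the 5% aimed at for DMRTA1 (8.9%), TBR1 (9.3%), PITX1 (8.2%) and LMO2 (5.3%), and was 4.7% for OVOL1 and for ZBTB7C. A single draw does not show how far these shares vary.

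Total estimated counts per library were 23511362 to 34365408 in the DMRTA1 set, 11763962 to 13745675 in the TBR1 set, 26691709 to 34532875 in the OVOL1 set and 27099757 to 36818063 in the set of the other 3 genes. The share of reads in no feature, which entered no library size or test, was 13.7% to 23.6%, 51.6% to 56.9%, 12.6% to 17.1% and 20.2% to 29.9% in the same order. The biological coefficient of variation was 8.89% in the DMRTA1 fit, 25.1% in the 10 organoid libraries, 7.22% in the OVOL1 fit and 8.41% in the 12 libraries of the other trophoblast set. Reads of genes with near-identical copies (CGB, PSG, ERVV and galectin genes, LRRC37A3, PI4KAP1) can be split between copies, and strand use is not stated, so antisense and overlapping genes cannot be separated.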

Results

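Gene expression was measured by RNA-seq in 28 cultures derived from KOLF2.2J, an established human induced pluripotent stem cell line. Of these, 10 were organoids of cortical type and 18 were cells taken along the trophoblast lineage to a primitive syncytium, the early fused layer of the placenta. All were labelled day 6. The edited clones carried a termination codon in DMRTA1 or TBR1 (organoids) or in OVOL1, PITX1, LMO2 or ZBTB7C (trophoblast), with 3 clones per gene. No unedited clone was among the samples. In every comparison the edit therefore cannot be told apart from the isolation and culture of clones. The effect of an edit below means edited clones against parental libraries. The DMRTA1 clones had 3 parental libraries in their set and the TBR1 clones had 1. The OVOL1 clones had 3, and the PITX1, LMO2 and ZBTB7C clones shared another 3. Total estimated counts per library ran from 11763962 to 13745675 in the TBR1 set and from 23511362 to 36818063 in the other sets.

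The transcript of the targeted gene was lower in every edited library than in every parental library of its set for 5 of the 6 genes. OVOL1 had 50.7 ± 4.91 CPM (SD, n = 3 clones) against 419 ± 16.9 CPM (n = 3 parental libraries), a log2 fold change of -3.04 ± 0.07 (SE). DMRTA1 had 80.3 ± 3.56 against 151 ± 19.8 CPM, a log2 fold change of -0.91 ± 0.09. ZBTB7C had 71.2 ± 4.84 against 126 ± 1.64 CPM, a log2 fold change of -0.82 ± 0.06, and LMO2 had 33.8 ± 2.13 against 45.9 ± 0.633 CPM, a log2 fold change of -0.44 ± 0.07. The adjusted p of edgeR's quasi-likelihood test was 8.44e-16 for OVOL1, 0.0145 for DMRTA1, 1.83e-06 for ZBTB7C and 0.0175 for LMO2. The call on DMRTA1 was lost without clone C11 (adjusted p = 0.122), without F09 (0.129) and with all organoid libraries in the fit (0.173), while its lowest adjusted p was 2.63e-17. That on LMO2 was lost without clone F07 (0.135) and without parental library 1, 2 or 3 (0.176, 0.115 and 0.0749), its lowest adjusted p being 1.75e-05. PITX1 had 5.19 ± 1.81 against 17.3 ± 1.25 CPM, a log2 fold change of -1.75 ± 0.25 with an adjusted p of 0.133, and its adjusted p ran from 1.17e-46 to 0.449 over 11 alternatives, with 0.0428 when clone B03 was left out. TBR1 had 14.1 CPM in clone A01, 39.0 CPM in clone B03 and 38.1 CPM in clone C10 against 11.6 CPM in the lone parental library, with an adjusted p of 0.372 (0.000141 without clone A01, and up to 0.895 over the alternatives). The edits lie in exon 1 of DMRTA1 (chromosome 9, 22447390 to 22447392) and of TBR1 (chromosome 2, 161416702 to 161416704) and in exon 3 of OVOL1 (chromosome 11, 65794648 to 65794650). Those of the others lie in exon 2 of PITX1 (chromosome 5, 135031447 to 135031449), of LMO2 (chromosome 11, 33864673 to 33864675) and of ZBTB7C (chromosome 18, 48040844 to 48040846). In the annotation the edit falls in a coding exon of 1 of 3 coding transcripts of TBR1, 2 of 3 of LMO2 and 4 of 28 of ZBTB7C, and of all coding transcripts of the other genes. No protein was measured. A termination codon need not lower the transcript, so a level near that of the parental line does not speak against an edit.

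**Figure D1:**
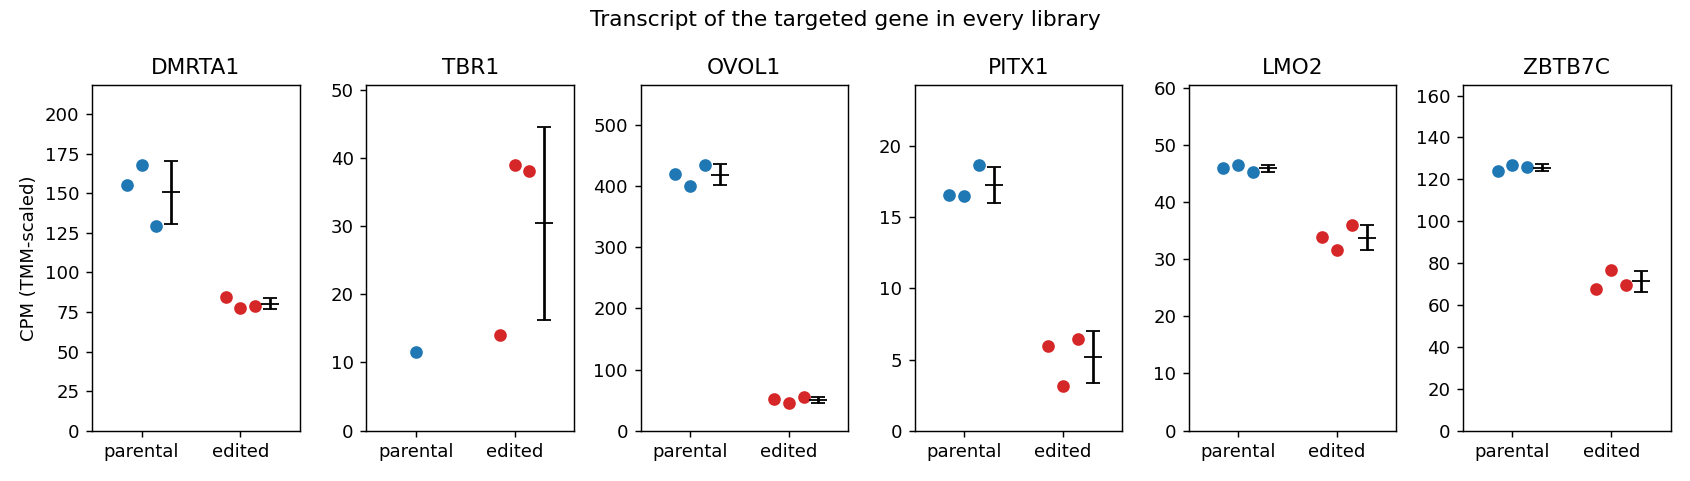
TMM-scaled CPM of the targeted gene (vertical axis, linear from 0) in each parental library (blue) and each edited clone (red) of its set. Bars are means with SD where there are 3 libraries. The edited clones lie below all parental libraries for every gene but TBR1, where they lie at 14.1, 39.0 and 38.1 against 11.6 CPM.

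The DMRTA1 comparison asked how organoids change with an edit in this DM-domain transcription factor gene of the dorsal forebrain. Organoids of the 3 clones had higher levels of POU4F1, a sensory neuron transcription factor (log2 fold change 1.56 ± 0.23, 6.30 ± 2.06 against 2.14 ± 0.101 CPM), of the immediate early gene FOSB (1.93 ± 0.27) and of the stress-inducible GADD45B (1.97 ± 0.23) and GADD45G (1.45 ± 0.29). FGF8, a signal of the rostral forebrain and isthmus, fell from 4.91 ± 1.52 to 1.74 ± 0.121 CPM, and ESRP1, an epithelial splicing regulator, fell by 2.14 ± 0.41. GAD1, the GABA-synthesizing enzyme, rose by 1.33 ± 0.28. In all, 452 of 16337 genes passed edgeR's test at an adjusted p under 0.05, 183 higher and 269 lower, and 77 of them changed at least 2-fold. The groups of 3 did not overlap for 31.5% of the genes. Chance gives 10% on average over splits, but genes that vary together can take a single split above that. The share was 19.7% for PITX1, 22.1% for LMO2 and 26.2% for ZBTB7C, where 1, 37 and 64 genes were called.

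Besides these, the named genes that rose were the potassium channel KCNA1 (2.20 ± 0.42), the synaptic vesicle protein SV2C (1.69 ± 0.37), PCDH10, ACTA1, OLFM3 and LAMP5, the last 4 by 1.26 to 1.36. Those that fell were MBP (by 1.53 ± 0.23), the collagen COL6A3 (by 1.44 ± 0.30), VAMP8, ITPR3, TC2N, BCHE, TESMIN and POU6F2, the last 6 by 1.26 to 1.35. Their adjusted p values lay between 0.0159 and 0.049.

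Among the preset lists, surface ectoderm and epithelium genes shifted down in the DMRTA1 clones. Of 16 measured members 2 fell, ESRP1 and the tight junction gene CLDN6 (by 0.59 ± 0.10), and 14 were not called, while 10 fell when adjusted over the list alone. The list's median log2 fold change was -0.41 with a camera adjusted p of 0.00017, and adjusted p = 0.586 with an estimated correlation. The pluripotency list also shifted down (median -0.17, adjusted p = 0.00117), with none of 12 members called over all genes or adjusted over the list alone, and adjusted p = 0.586 with an estimated correlation. Its mean log2 CPM was 2.11 in clone B11, 1.83 in C11 and 1.90 in F09, against 2.10 to 2.21 in the parental libraries, so B11 lay in the parental range. For surface ectoderm it was 0.57, 0.54 and 0.80 against 0.76 to 0.98, with F09 in the parental range. Of 20 p53 targets 3 fell, BTG2 (by 0.42 ± 0.09), CCNG1 and RRM2B, or 5 fell and 1 rose when adjusted over the list alone, and the list shifted down (median -0.13, adjusted p = 0.0339, and adjusted p = 0.593 with an estimated correlation). Without clone B11, clone C11 or parental library 4 that list was not called (adjusted p 0.121, 0.124 and 0.0891, with 0.00137 the lowest of its alternatives). Clone F09, at 4.71, lay in its parental range of 4.64 to 4.72, with B11 at 4.57 and C11 at 4.55.

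WNT targets and cholesterol synthesis genes shifted up in the DMRTA1 clones. None of the 15 WNT targets was called over all genes and 5 rose when adjusted over the list alone (median 0.41, adjusted p = 0.00498, and adjusted p = 0.593 with an estimated correlation). TNFRSF19 had 89.2 against 48.1 CPM (adjusted p = 0.0894). None of the 20 cholesterol synthesis genes was called either way (median 0.32, adjusted p = 0.00117, and adjusted p = 0.593 with an estimated correlation). Per library, the mean log2 CPM of the WNT list was 3.20 in clone B11, 4.07 in C11 and 4.17 in F09, against 2.98 to 3.28 in the parental libraries. For cholesterol synthesis it was 4.78, 5.29 and 5.44 against 4.71 to 4.90. Of 17 dorsal telencephalon genes 1 was called, DMRTA1 itself, or 2 higher and 5 lower when adjusted over the list alone, and no cell cycle gene of 25 was called. The number of genes called rested on single libraries: it was 1042 without clone B11, 2 without C11, 1 without F09, 725 without parental library 1 and 13 without parental library 4. It was 0 by edgeR with all 10 organoid libraries in the fit and 1135 by DESeq2. None of the 33 called genes that were followed stayed called under every alternative.

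In the TBR1 set, clone A01 resembled the parental library while clones B03 and C10 lay apart from both. TBR1 encodes a T-box factor of early cortical neurons. Over 16526 genes the root mean square difference in log2 CPM was 0.379 between A01 and the parental library, 0.472 between B03 and C10, 1.26 between B03 and the parental library and 1.22 between C10 and the parental library. Mean log2 CPM of the neuron list was 3.77 in A01, 3.40 in B03, 3.56 in C10 and 3.73 in the parental library, and of neuroectoderm genes 5.21, 4.98, 4.67 and 5.35. Interferon response genes had -0.03, 2.07, 1.89 and 0.12, and pluripotency genes -0.36, 0.63, 0.24 and -0.44, in the same order. Lists of other lineages were also higher in B03 and C10. Mesoderm and endoderm genes had -2.00, -0.22, -0.39 and -1.89, and syncytiotrophoblast genes -2.59, -1.70, -1.66 and -2.54. Notch pathway genes were lower there, with 4.60, 4.15, 4.18 and 4.72. Genes with at least 10 counts numbered 16158, 18229, 17826 and 16225. The rise was thus not particular to interferon and pluripotency genes. Heat shock genes, listed after the data were seen, had 7.45, 9.48, 9.61 and 7.43.

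As a group of 3, the TBR1 clones gave 0 of 21621 genes at an adjusted p under 0.05 by edgeR against the lone parental library, in a fit of all 10 organoid libraries, with 2887 at an unadjusted p under 0.05, and DESeq2 called 120 (102 higher, 18 lower). Camera called the cholesterol synthesis list lower over the 3 clones as a group (median -0.42, none of 20 members called over all genes or adjusted over the list alone, adjusted p = 0.00838, and adjusted p = 0.869 with an estimated correlation). Its mean log2 CPM was 8.04 in A01, 7.43 in B03, 6.97 in C10 and 8.04 in the parental library, so A01 did not share the shift, and without B03 and C10 the direction turned (adjusted p = 0.883). The neuroectoderm list was also called lower (adjusted p = 0.0318, and adjusted p = 0.869 with an estimated correlation), with a median of -0.39 but a mean of 0.01 over its 22 members, none of them called over all genes or adjusted over the list alone. Without clone C10 neither list was called (adjusted p = 0.204 for both), and without B03 the neuroectoderm list was not (0.0567), while over all alternatives the adjusted p ran from 0.00087 to 0.883 and from 0.00433 to 0.918. Without clone A01, 8605 genes were called.

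**Figure D2:**
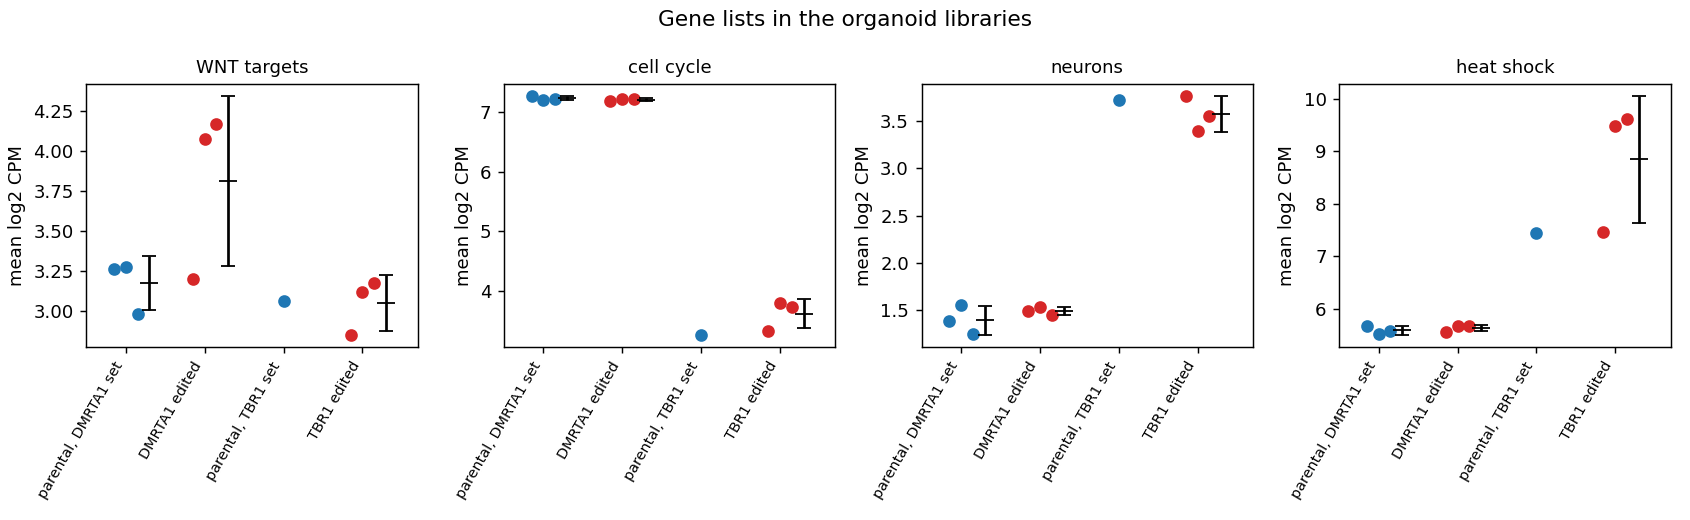
Mean log2 CPM of 4 gene lists (vertical axes) in each organoid library, parental in blue and edited in red, with means and SD for groups of 3. On the heat shock list TBR1 clones B03 and C10 lie at 9.48 and 9.61 and clone A01 at 7.45, beside the parental library at 7.43.

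The OVOL1 comparison asked how the trophoblast cells change with an edit in this zinc-finger transcription factor gene of epithelial and trophoblast differentiation. Most listed transcripts of the differentiated syncytiotrophoblast, the hormone-producing fused layer of the placenta, fell. CGA, the alpha chain of chorionic gonadotropin, fell by 3.28 ± 0.14 on the log2 scale, and the beta chain gene CGB5 fell by 8.60 ± 0.13 (0.402 ± 0.0664 against 157 ± 16.5 CPM), with reads that near-identical CGB copies can share. The envelope gene ERVW-1, which encodes the fusogen syncytin, fell by 2.78 ± 0.09 and ERVFRD-1 fell by 4.27 ± 0.13. In all, 9198 of 15232 genes were called by edgeR, 4685 higher and 4513 lower. Of these, 627 were at least 2-fold higher and 1554 at least 2-fold lower. Which direction had more calls rested on the settings. There were 4395 higher and 4686 lower with median-of-ratios factors, 3954 and 4451 by DESeq2, and 5083 and 4817 in the featureCounts table. The groups did not overlap for 65.4% of genes, where chance gives 10% on average over splits.

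Of 33 measured syncytiotrophoblast genes 29 fell in the OVOL1 clones, OVOL1 itself among them, 2 rose and 2 were not called, or 30 fell and 2 rose when adjusted over the list alone (median -2.78, camera adjusted p = 1.62e-11, and adjusted p = 0.343 with an estimated correlation). The T-box factor TBX3 fell by 2.95 ± 0.07 (124 against 958 CPM) and ENDOU by 7.24 ± 0.13, while the growth factor-binding protein protease PAPPA2 rose by 1.84 ± 0.08 and INHBA rose by 0.90 ± 0.18. GCM1, a driver of syncytial fusion, fell by 0.62 ± 0.07, and the aromatase CYP19A1 fell by 0.34 ± 0.08. All 10 measured members of families with near-identical copies (CGB, PSG, ERVV and galectin genes) fell, with a median of -3.98, and of the 23 others 19 fell and 2 rose, with a median of -1.97.

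Steroid synthesis genes of the same cells also fell, 9 of 12 with 2 rising, or 10 and 2 when adjusted over the list alone (median -0.48, adjusted p = 0.0362, and adjusted p = 0.869 with an estimated correlation), and the list was not called with no filter on low counts (0.131) or in the featureCounts table (0.106), the lowest of its alternatives being 0.0128. HSD11B2, which inactivates cortisol, fell by 4.80 ± 0.11 (2.75 against 77.0 CPM) and HSD3B1, which makes progesterone, fell by 1.97 ± 0.07. HSD3B1, CYP19A1 and HSD17B1, all lower, are also on the syncytiotrophoblast list, so these lists are not independent. The same holds for ERVW-1, ERVFRD-1 and ERVV-1, which are on the cell fusion list too. Of 17 cell fusion and membrane remodelling genes 8 fell, ANXA1 and DYSF among them, 4 rose and 5 were not called, with the same numbers up and down when adjusted over the list alone (adjusted p = 0.191). Unfolded protein and integrated stress response genes fell in 13 of 17 cases with 1 rising, over all genes and adjusted over the list alone (median -0.94, adjusted p = 0.000187, and adjusted p = 0.343 with an estimated correlation). HERPUD1 fell by 2.22 ± 0.07 and XBP1 by 1.49 ± 0.07.

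BMP targets fell in 8 of 11 cases with 2 rising in the OVOL1 clones, over all genes and adjusted over the list alone (median -0.79, adjusted p = 0.0254, and adjusted p = 0.343 with an estimated correlation). The inhibitory SMAD7 fell by 2.99 ± 0.07 and ID4 by 2.65 ± 0.08. Interferon response genes fell in 17 of 18 cases, or all 18 when adjusted over the list alone (median -2.22, adjusted p = 4.15e-09, and adjusted p = 0.308 with an estimated correlation). MX1 fell by 4.33 ± 0.09 (7.42 against 150 CPM) and ISG15 by 3.13 ± 0.09. On this list the OVOL1 clones had a mean log2 CPM of 1.13 to 1.26 and their parental libraries 2.87 to 3.03, where the 12 libraries of the other trophoblast set had 1.28 to 1.95.

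Other trophoblast genes went both ways in the OVOL1 clones. Of 26 cytotrophoblast and stem cell genes 13 rose, 11 fell and 2 were not called, or 13 and 12 when adjusted over the list alone (camera adjusted p = 0.741). The imprinted gene PEG10 rose by 1.90 ± 0.08 and the Hippo pathway factor YAP1 by 1.08 ± 0.07, while TFAP2C fell by 1.92 ± 0.07 and GATA2 by 1.29 ± 0.08. Among 25 extravillous trophoblast genes 8 rose, ASCL2 (by 3.36 ± 0.27) among them, and 13 fell, or 9 and 13 when adjusted over the list alone (adjusted p = 0.672). Of 25 cell cycle genes 15 rose and 8 fell over all genes and adjusted over the list alone (adjusted p = 0.562). The endothelial cadherin CDH5 fell by 3.60 ± 0.08 (68.5 against 831 CPM), and the VEGF receptor FLT1 rose by 2.51 ± 0.20. FLT1 was lower in this set's parental libraries than in those of the other trophoblast set. For it a low parental level and a rise with the edit cannot be told apart.

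The largest rises by the naming rule in the OVOL1 clones were of FMO9P (4.77 ± 0.25, 5.25 against 0.189 CPM), the death ligand TNFSF10 (4.23 ± 0.30), FILNC1 (3.50 ± 0.12), ASCL2, the sphingosine phosphate receptor S1PR1 (3.27 ± 0.20), LIPH, APBB1IP (2.98 ± 0.08, 57.0 against 7.20 CPM), ALOX15B, MYBPC2 and CAMK2N1. TNFSF10 was lower in this set's parental libraries than in those of the other trophoblast set. Some transcripts were near absent in the clones. TCL1B had 45.3 ± 5.86 CPM in the parental libraries and 4 reads over the 3 clones, TPPP3 had 28.5 ± 2.74 CPM and 3 reads, SLC1A2, a glutamate transporter, had 17.2 ± 1.18 CPM and 3 reads, SBSN had 14.0 ± 0.608 CPM and 1 read, and the hormone gene GAST had 1136 reads over the 3 parental libraries and 1 over the clones. The phosphatase PHOSPHO1 fell from 96.3 ± 12.1 to 0.147 ± 0.111 CPM, the calcium pump ATP2A3 from 42.7 ± 4.32 to 0.0763 ± 0.073 CPM, THEM5 from 21.5 ± 2.57 to 0.106 ± 0.0671 CPM and ELFN2 from 13.5 ± 1.66 to 0.0693 ± 0.041 CPM. Clone A02, whose description names an organoid while its title names the trophoblast, had mean log2 CPM of 1.99 for syncytiotrophoblast and -1.42 for neuroectoderm genes, beside 1.91 and 2.04, and -1.69 and -1.58, in the other OVOL1 clones, while organoid libraries had 4.67 to 5.84 for neuroectoderm genes. The share of reads in no feature was 12.6% to 13.1% in the clones and 15.2% to 17.1% in their parental libraries. Divergent transcripts went the other way, with 292 to 339 plain CPM in the clones and 265 to 283 in the parental libraries.

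**Figure D3:**
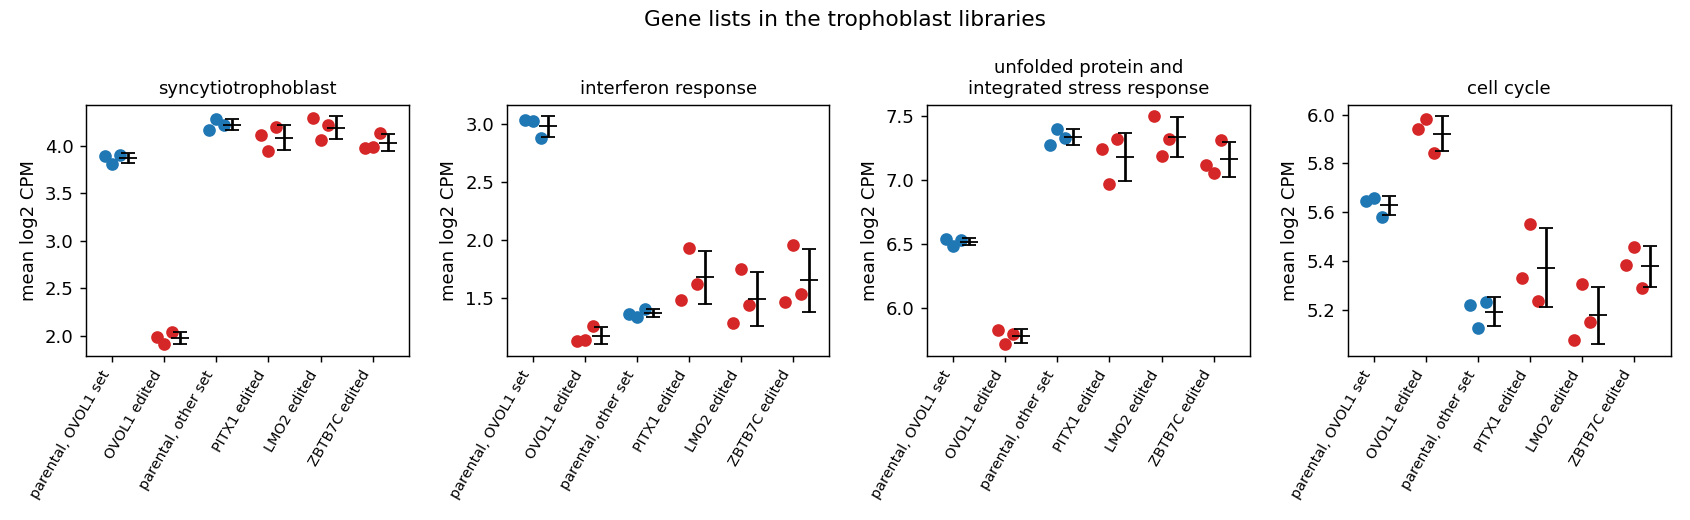
Mean log2 CPM of 4 gene lists (vertical axes, not from 0) in each trophoblast library, parental in blue and edited in red, with the mean and SD of each group of 3. The OVOL1 clones lie at 1.91 to 2.04 on the syncytiotrophoblast list, below their parental libraries at 3.81 to 3.90.

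In the PITX1 comparison, 1 of 16469 genes was called by edgeR, the neuronal ubiquitin ligase gene TRIM9, which fell by 0.63 ± 0.08 (29.6 ± 1.85 against 45.7 ± 1.31 CPM, n = 3 and 3, adjusted p = 0.00393). PITX1 is a homeodomain factor of hindlimb and pituitary development. The syncytiotrophoblast list shifted down (median -0.18, none of 36 members called over all genes and 3 lower when adjusted over the list alone, camera adjusted p = 3.6e-06, and adjusted p = 0.635 with an estimated correlation). The fusogen ERVFRD-1 had 354 against 443 CPM (adjusted p = 0.24). Unfolded protein and integrated stress response genes shifted down (median -0.22, none of 17 called and 3 lower when adjusted over the list alone, adjusted p = 1.94e-05, and adjusted p = 0.635 with an estimated correlation), as did BMP targets (median -0.08, none of 13 called over all genes or adjusted over the list alone, adjusted p = 0.0349, and adjusted p = 0.635 with an estimated correlation). Cell cycle genes shifted up (median 0.15, none of 25 called over all genes or adjusted over the list alone, adjusted p = 0.00789, and adjusted p = 0.635 with an estimated correlation).

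On these lists PITX1 clone B03 lay furthest from the parental libraries, with mean log2 CPM of 3.95 for syncytiotrophoblast genes, 6.97 for unfolded protein and integrated stress response genes and 5.55 for cell cycle genes. Clones A01 and C03 had 4.12 and 4.20, 7.25 and 7.32, and 5.33 and 5.23, and the parental libraries 4.17 to 4.29, 7.28 to 7.40 and 5.12 to 5.23. For BMP targets only clone B03, at 3.955, lay below the parental libraries (4.371 to 4.427). Clone C03, at 4.407, lay in their range and A01, at 4.449, above it. Clone B03 also had a lower share of reads in no feature (20.2% against 21.8% to 25.0% in the parental libraries, 26.2% in A01 and 26.9% in C03), a lower CPM of olfactory receptor genes (6.74 against 7.45 to 9.74), and a CPM of divergent transcripts below the lowest parental value of 368. In A01 and C03 both measures lay above every parental library, with 9.96 and 10.6 CPM of olfactory receptor genes and divergent transcripts above the highest parental value of 381 CPM. Without clone B03 the BMP and cell cycle lists were not called (adjusted p 0.606 and 0.492), nor were they without parental library 2 (0.0673 and 0.0581), nor the BMP list without parental library 3 (0.0815). The lowest adjusted p over their alternatives was 0.00927 for BMP and 0.000357 for cell cycle. TRIM9 was not called without parental library 3, when its adjusted p, from 1.29e-10 over the other settings, reached 0.0673. At an unadjusted p under 0.05 there were 2028 genes. DESeq2 gave an adjusted p for 4115 genes, TRIM9 not among them, and called 109, while edgeR called 2 without clone A01 or B03 and 0 without parental library 3.

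LMO2 encodes a LIM-only cofactor known from blood formation. In its clones 37 of 16469 genes were called by edgeR, 2 higher and 35 lower. The share of higher genes rested on the settings, with 260 higher and 223 lower with no filter on low counts, 114 and 145 with other samples in the fit, and 84 and 151 without PITX1 clone B03 and ZBTB7C clone A11. DOCK5, a guanine nucleotide exchange factor, rose by 0.42 ± 0.07 and the histone demethylase KDM4B by 0.39 ± 0.07. OMG fell by 1.05 ± 0.19 (3.13 ± 0.837 against 6.48 ± 1.31 CPM, n = 3 and 3), AGFG2 by 0.86 ± 0.13, the sulfotransferase SULT2A1 by 0.84 ± 0.16 and SGMS2, a sphingomyelin synthase, by 0.75 ± 0.14. FAM118B, PKIA, the pattern receptor CLEC7A, the growth factor HBEGF, LRRC37A3 (a gene with near-identical copies) and PHOSPHO1 fell by 0.45 to 0.50, with adjusted p values of 0.0246 to 0.0472. The cyclin CCNB1 fell by 0.28 ± 0.06.

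The hypoxia and glycolysis list shifted up in the LMO2 clones (median 0.24, none of 21 members called over all genes or adjusted over the list alone, camera adjusted p = 1.63e-05, and adjusted p = 0.925 with an estimated correlation). PFKFB4 had 61.2 against 52.2 CPM (adjusted p = 0.185). In every LMO2 clone the share of reads in no feature (25.0% to 29.9% against 21.8% to 25.0%), the CPM of olfactory receptor genes (at least 10.2 against 7.45 to 9.74) and that of divergent transcripts (414 to 472 against 368 to 381) lay above every parental library. The number of genes called was 109 without clone A06, 1 without F07, 8 without F08, 0 without parental library 1 or 2 (by edgeR) and 9 without parental library 3. None of 14 called genes that were followed held whichever library was left out. By DESeq2 the number was 312, and 2207 genes had an unadjusted p under 0.05.

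ZBTB7C encodes a zinc-finger and BTB-domain factor. In its clones the itch receptor gene MRGPRX1, of a family of similar genes, rose by 0.76 ± 0.06 (283 ± 19.9 against 167 ± 3.96 CPM, n = 3 and 3), DPF3, a chromatin remodelling subunit, by 0.76 ± 0.09, the ligand WNT6 by 1.13 ± 0.17 and the mucin MUC16 by 0.72 ± 0.12. The ubiquitin-conjugating enzyme UBE2J1 fell by 0.53 ± 0.06, AKR1B1, an aldose reductase, by 0.49 ± 0.07, the desmosomal cadherin DSG1 by 1.53 ± 0.26 and RUNX1, a transcription factor, by 0.34 ± 0.06. In all, 64 of 16469 genes were called by edgeR, 18 higher and 46 lower. AASS, ATP6V1B1, the kinetochore gene CENPF, the collagen COL27A1, PVT1 and MCAM rose by 0.44 to 0.58. PP12613, GABRR2, the small heat shock protein CRYAB, WDR47, POF1B, BCAR3 and LIMCH1 fell by 0.53 to 0.92. The calls on ZBTB7C, DPF3, MRGPRX1, COL27A1, UBE2J1 and AKR1B1 held in every alternative run.

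Among the lists, unfolded protein and integrated stress response genes shifted down in the ZBTB7C clones (median -0.21, none of 17 called and 1 lower when adjusted over the list alone, camera adjusted p = 0.000244, and adjusted p = 0.641 with an estimated correlation). Syncytiotrophoblast genes did too (median -0.20, none of 36 called and 1 lower when adjusted over the list alone, adjusted p = 0.000999, and adjusted p = 0.641 with an estimated correlation). CYP19A1 had 1149 against 1343 CPM (adjusted p = 0.153). BMP targets shifted down (median -0.16, none of 13 called over all genes or adjusted over the list alone, adjusted p = 0.0471, and adjusted p = 0.641 with an estimated correlation). Cell cycle genes shifted up (median 0.12, none of 25 called, 3 higher and 1 lower when adjusted over the list alone, adjusted p = 0.00355, and adjusted p = 0.641 with an estimated correlation), as did interferon response genes (median 0.31, none of 15 called and 1 higher when adjusted over the list alone, adjusted p = 0.0417, and adjusted p = 0.641 with an estimated correlation).

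Clone B10 lay in the parental range for unfolded protein and integrated stress response genes (mean log2 CPM of 7.31 against 7.28 to 7.40) and BMP targets (4.41 against 4.37 to 4.43), and A09 and A11 lay below both ranges. All 3 clones lay below the parental libraries for syncytiotrophoblast genes and above them for cell cycle genes. Divergent transcripts had 423, 390 and 405 CPM in A09, A11 and B10, above every parental library (368 to 381). The share of reads in no feature was 28.6%, 22.8% and 25.0% in these clones and 21.8% to 25.0% in the parental libraries. On the interferon list ZBTB7C clone A11 had a mean log2 CPM of 1.95, clones A09 and B10 had 1.46 and 1.53, and the parental libraries 1.34 to 1.40. Without A11 the interferon, cell cycle and BMP lists were not called (adjusted p 0.264, 0.0659 and 0.115), without A09 the BMP list was not (0.152), and neither interferon nor BMP was without parental library 2 (0.0972 for both), nor interferon without library 1 (0.0895), nor BMP without library 3 (0.103). The lowest adjusted p over their alternatives was 0.00277, 0.000941 and 0.0044. The number of genes called was 24 without A09, 13 without A11, 16 without parental library 1 or 2 and 12 without library 3, and it was 433 by DESeq2.

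Compared with each other, the PITX1 and LMO2 clones differed in 0 of 16469 genes by edgeR, with 3190 at an unadjusted p under 0.05 and 557 called by DESeq2, and without PITX1 clone C03 edgeR called 1016, and without PITX1 clone A01 or LMO2 clone F08 it called 1. PITX1 and ZBTB7C clones differed in 7 genes, or in 4 without PITX1 clone A01, 20 without B03, 3 without ZBTB7C clone A11 and 4 without B10. ZBTB7C itself was higher in the PITX1 clones (0.69 ± 0.06), and MRGPRX1 (-0.68 ± 0.06), MCAM (-0.50 ± 0.08), NFATC3 (-0.45 ± 0.06), COL27A1 (-0.40 ± 0.07) and the pseudogene PI4KAP1 (-0.36 ± 0.06), which shares sequence with its parent gene, were lower. LMO2 and ZBTB7C clones differed in 74 genes, 43 higher and 31 lower in the LMO2 clones, or in 35 without LMO2 clone A06, 16 without F08, 11 without ZBTB7C clone A09 or A11 and 327 without B10. WNT5A (0.87 ± 0.13), DSG1 (1.35 ± 0.26), FRMPD1, DENND2C and GABRR2 were higher there, and the microtubule-associated MAP1A (-0.62 ± 0.07), WNT6 (-0.92 ± 0.17), MUC16, DPF3 and AASS were lower. Of the genes named for these pairs, ZBTB7C, MRGPRX1 and MAP1A stayed called under every alternative.

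LMO2 and ZBTB7C clones shared 3 lower genes, RBM24, CLEC7A and GAB1, where lists drawn independently would share 0.0978, a number that leaves out the parental libraries they have in common. Over 16469 genes, which are not independent replicates, the log2 fold changes of PITX1 and ZBTB7C clones correlated with r = 0.645, against 0.513 for simulated unchanged groups, and their covariance was 0.0575 against 0.0302. For LMO2 and ZBTB7C r was 0.397 against 0.514 and the covariance 0.0367 against 0.0311, and for PITX1 and LMO2 r was 0.37 against 0.509 and the covariance 0.0298 against 0.0302. The 3 shared parental libraries are too few to split. The simulated groups share parental libraries as well, so the PITX1 and ZBTB7C excess is over what sharing gave there. Genes were drawn independently, so co-variation among libraries was not simulated. PITX1 clone B03 and ZBTB7C clone A11 differed by a root mean square of 0.263 log2 CPM. Clone B03 differed from PITX1 clones A01 and C03 by 0.332 and 0.374, so part of that excess may come from this likeness.

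The effect of the OVOL1 edit differed from the mean effect of the PITX1, LMO2 and ZBTB7C edits in 7477 of 16875 genes by edgeR, 3463 more positive and 4014 more negative. FILNC1 (difference 3.68 ± 0.19), TNFSF10 (4.03 ± 0.66), S1PR1 (3.41 ± 0.33), GOLGA7B (3.04 ± 0.28) and EDNRA (3.03 ± 1.07, adjusted p = 0.0345, up to 0.114 when single libraries were left out) were the most positive by the naming rule, and PHOSPHO1, TPPP3, TCL1B, SBSN and GAST the most negative, all 5 near absent in the OVOL1 clones. These sets differ in lane and parental libraries too. TNFSF10 and EDNRA were lower in the OVOL1 set's parental libraries than in the other set's. For them a low parental level and a rise with the edit cannot be told apart. The parental line itself differed between the trophoblast sets in 10382 of 16875 genes, 5222 higher and 5160 lower in the OVOL1 set. There the peptide hormone gene NPPB (3.89 ± 0.27), ACTA1 (3.87 ± 0.43), TGFB2 (3.59 ± 0.31), IL32 (3.49 ± 0.21) and the interferon-induced IFIT1 (3.43 ± 0.37) were higher, and PPFIA4 (0.0556 against 2.91 CPM, with 5 reads in the OVOL1 set), TNFSF10 (-5.30 ± 0.54), FLT1 (-4.89 ± 0.51, 2.37 ± 0.0679 against 70.3 ± 16.2 CPM), EDNRA (-4.23 ± 0.84) and the water channel AQP1 (-3.90 ± 0.56) were lower.

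The effects of the DMRTA1 and TBR1 edits in organoids differed in 0 of 21621 genes by edgeR, with 2316 at an unadjusted p under 0.05, and DESeq2 called 70. On simulated counts for this comparison (18603 genes), edgeR recovered 0% of genes changed 2-fold and 24.2% of those changed 4-fold. The count of 0 therefore does not show that the effects were alike. The median difference over all genes was -0.12, and without TBR1 clone A01 edgeR called 5940 genes.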

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

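The 3 comparisons between groups named next were planned, and every other test in this part was chosen after the results were seen. Effects under the same edit-against-parental contrast differed between groups in 3 tests of the difference: 7 genes between PITX1 and ZBTB7C clones, 74 between LMO2 and ZBTB7C clones, and 7477 between the effect of the OVOL1 edit and the mean effect of the other 3 trophoblast edits. The first 2 sets share parental libraries, and the last comes from sets that also differ in lane and parental cultures.

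With 3 libraries a side there are 10 ways to split 6 libraries, too few for a share under 0.05. For the edits against the parental line, the splits with as many calls, the real one included, were 1 of 10 for DMRTA1 (452 genes, highest other split 0), 1 of 10 for OVOL1 (9198, highest other 0), 2 of 10 for PITX1 (1, highest other 1), 1 of 10 for LMO2 (37, highest other 0) and 1 of 10 for ZBTB7C (64, highest other 0). Between edits they were 10 of 10 for PITX1 and LMO2 (0, highest other 0), 3 of 10 for PITX1 and ZBTB7C (7, highest other 428) and 1 of 10 for LMO2 and ZBTB7C (74, highest other 1), and for the parental line between the trophoblast sets 1 of 10 (10382, highest other 0). For OVOL1 against the mean of the others, 4 of 40 label draws had as many calls (7477, highest other 8059). There 7 draws kept or mirrored the OVOL1 labels and gave 6706 to 8059 genes, and the rest gave 0. The split with 428 genes set PITX1 clones A01 and C03 with ZBTB7C clone B10 against PITX1 clone B03 with ZBTB7C clones A09 and A11, which points to structure among these libraries other than the edited gene.

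TBR1 clones B03 and C10 lay apart from clone A01 and the parental library. Clone A01 differed from the parental library by a root mean square of 0.379 log2 CPM, less than the 0.472 between B03 and C10, but this restates the pattern with 1 clone and 1 parental library, so loss of TBR1 stays open. Genomic DNA or transcription outside genes could raise silent gene families, and olfactory receptor CPM was 2.25 times as high, but cells under stress may also read through gene ends, so this stays open. Other library measures split the same way. In A01, B03, C10 and the parental library, reads in no feature were 53.4%, 56.15%, 56.9% and 51.6%, and unmapped reads 3.66%, 5.51%, 5.12% and 3.74%. Mitochondrial counts were 1.53%, 0.53%, 0.80% and 1.55%, and divergent transcripts 2018, 3577, 3067 and 1979 plain CPM. The source of these library differences was not tested. A rise of 733 CPM per heat shock gene against 0.0314 CPM per olfactory receptor gene argues against evenly spread genomic DNA as the source of the heat shock rise. Silent genes do not gauge transcription beyond the ends of active genes, so that part stays open. Stress of the 2 cultures before lysis may explain a heat shock list 2.03 log2 CPM higher, yet those genes were chosen after the pattern was seen, and whether A01 is edited was not tested.

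Interferon response genes were lower in the OVOL1 clones than in their parental libraries. The highest clone, at 1.26 log2 CPM, lay just under the 1.28 to 1.95 of the 12 libraries of the other trophoblast set, so raised interferon activity in this set's parental cultures and a fall with the edit cannot be told apart.

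DMRTA1 clone B11 lay nearer to the parental libraries than C11 and F09 on the WNT target list. Over 14431 genes, B11 differed by a root mean square of 0.258 log2 CPM from parental library 2. It differed by 0.286 from C11 and 0.306 from F09, and by 0.370 and 0.352 from parental libraries 1 and 4. That B11 was not edited is argued against by its DMRTA1 level, 84.3 plain CPM against at least 128 in the parental libraries. The share of reads outside genes is argued against as well, since it varied by 0.33 percentage points over the clones and by 9.97 over the parental libraries. No biological explanation was tested.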

How the results depend on the processing

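Alternatives were fixed before the data were seen, except for leaving out TBR1 clones B03 and C10 together, or PITX1 clone B03 and ZBTB7C clone A11 together, which were chosen afterwards. No paired analysis was possible because edited clones carry clone names and no replicate numbers shared with parental libraries. Among results for single genes, 3819 stayed the same, 198 became stronger, 369 weaker and 1 reversed, and among lists 199 stayed the same, 48 became weaker and 1 reversed. A gene called in neither setting counts as the same, so this tally overstates how well calls held. Of the called genes followed, 100 of 100 kept the call in every alternative for OVOL1. The number was 6 of 22 for ZBTB7C, 0 of 33 for DMRTA1, 0 of 14 for LMO2 and 0 of 1 for PITX1. Every called list lost its call with the estimated correlation. The reversed ones were ASNS in the DMRTA1 comparison in the featureCounts table (log2 fold change 0.30) and the cholesterol synthesis list in the TBR1 comparison without clones B03 and C10 (adjusted p = 0.883), and the cause was not tested. The numbers of genes called for OVOL1 (8188 to 9900), OVOL1 against the mean of the others (6602 to 8322) and the parental line between sets (9523 to 12138) stayed within 1.5 times the main value. With no filter on low counts, the number was 1476 for DMRTA1, 396 for PITX1, 483 for LMO2, 820 for ZBTB7C, 1463 between PITX1 and LMO2, 114 between PITX1 and ZBTB7C, 1509 between LMO2 and ZBTB7C and 1 between the organoid effects. DESeq2 called 1135 for DMRTA1, 120 for TBR1, 109 for PITX1, 312 for LMO2, 433 for ZBTB7C, 557, 34 and 619 between the same pairs and 70 between the organoid effects. The featureCounts table gave 3 for PITX1, 128 for ZBTB7C and 2 between these. With other samples in the fit there were 0 for DMRTA1, 259 for LMO2 and 1059 for ZBTB7C. Without PITX1 clone B03 and ZBTB7C clone A11 there were 3 for PITX1, 235 for LMO2, 104 for ZBTB7C, and 1, 4 and 186 between the pairs, and without TBR1 clones B03 and C10 there was 1 between the organoid effects. Leaving out single libraries gave 1 to 1042 for DMRTA1, 0 to 8605 for TBR1, 0 to 2 for PITX1, 0 to 109 for LMO2, 12 to 49 for ZBTB7C, 0 to 1016, 3 to 20 and 11 to 327 between the pairs, and 0 to 5940 between the organoid effects. The cause was not tested. TBR1 libraries had the lowest depth, from 11763962 to 13745675 estimated counts, and 51.6% to 56.9% of their reads in no feature. Whether depth limited the calls there was not tested.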

Other observations

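The organoid sets differed although all their libraries were labelled day 6. The parental library of the TBR1 set had mean log2 CPM of 3.73 for neuron genes against 1.24 to 1.55 in the DMRTA1 set's parental libraries, 3.26 against 7.21 to 7.28 for cell cycle genes, and -0.44 against 2.10 to 2.21 for pluripotency genes. Cholesterol synthesis genes had 8.04 against 4.71 to 4.90 and p53 targets 6.36 against 4.64 to 4.72. TBR1, a gene of early cortical neurons, had 12.5 plain CPM there against 0 to 0.0390. Set and lane cannot be separated from this difference, which was not tested.

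All 27 pairs of libraries within groups differed by more than sampling alone, with a median chi-square 1.86 to 34.9 times that of chance.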
